A study of Corynebacterium glutamicum R with 2 samples.

How the data were processed

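Chromatin immunoprecipitation followed by hybridization to tiling arrays (ChIP-chip) was carried out, per the labels, in Corynebacterium glutamicum R, a Gram-positive soil bacterium of the order Mycobacteriales. The cells had a wild-type background and expressed the sigma factor SigD with a FLAG tag. They were grown in rich medium with 1% glucose at 33 °C to an optical density of up to 2.5, treated with 1% formaldehyde for 20 min and quenched with 125 mM glycine. DNA was sheared to between 600 and 1000 bp on average. DNA recovered with an anti-FLAG antibody carried Cy5 and non-precipitated reference DNA of the culture carried Cy3 on both arrays, so red over green is IP over reference. The dyes were not swapped, so any dye bias left after normalization stays in the ratio. The labels describe 2 independent experiments, which form the only group (n = 2). The arrays came from different slides and scans, so slide and replicate cannot be separated. No array of an untagged strain was analysed here.

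Per the file headers, the deposited spot intensity values came from Agilent Feature Extraction 10.5.1.1, which subtracted background, detrended the surface and normalized the dyes with linear factors and a lowess fit. The deposited log10 ratio column equalled log10 of processed red over processed green. The deposited log2 value table equalled that column divided by log10 of 2, to within 1.39e-06, and was not centred again. Its column medians were 0 and 0.00971, and its scale and direction were settled by this match. No genome build is given in the sources used here.

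From the processed signals, log2(red/green) was computed per spot and centred on the median of each array, without loess or quantile normalization. Control spots and spots with non-uniformity or population outlier flags were left out, and the spots of a probe were averaged. Signal levels given below in percent of the array median kept the spots with outlier flags. The flags removed 5787 spots (13.2%) on array 1 and 3658 spots (8.35%) on array 2, of 43803 on each. A value on both arrays remained for 32912 of 40204 probes. No spot was saturated. Median background-subtracted reference intensity was 30563 and 28265 units and median IP intensity 71390 and 64668 units, against local backgrounds of 33 to 115 units. The number of arrays limits the precision.

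The tests were fixed before the data were examined. Probes were tested with limma 3.58.1 in R 4.3.3, with an intercept against 0, eBayes with trend and robust options and Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and a mean log2 ratio of 1 or more, or of -1 or less for depletion. Given a matrix of log ratios, limma fits the trend of the prior variance on the mean log ratio itself. This was the fit run first and it is the one reported. In simulated arrays of 32912 probes with 200 enriched probes, the fit recovered 195 at log2 of 1.2 and 200 at log2 of 2 when both arrays had the same height. It recovered 0 of 200 when the heights were 2 and 1.2, where eBayes without the trend recovered 200, with the robust option or without it. At heights of 3 and 1.8 it again recovered 0, eBayes without the trend but with the robust option 33, and eBayes without both options 200. The simulations with unequal heights were added after seeing the data.

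Enriched regions were planned in base pairs. Neither probe positions nor a genome of strain R were used here, so distances were counted in tiles, a change made after seeing the files. The 18462 forward and 18449 reverse tiles are numbered along the genome from opposite ends. The reverse tiles were placed on the forward numbering by the lag with the highest correlation in 34 windows of 1500 tiles. That lag ran from 2 to 11 tiles, with correlations of 0.23 to 0.51 at the chosen lag. The running mean took tiles within 1.5 tile numbers. A region was a run of at least 4 neighbouring tiles with a running mean of 1 or more on each array, and runs less than 3 tiles apart were joined. Chance was set by 1000 random rotations of array 2 along the numbering, with a one-sided permutation p, and by mirrored regions at -1 or less. In a simulation of 36911 tiles with 20 regions, 20 were recovered at single-tile heights of 2 and 1.5, 14 at 1.5 and 1.2, and 0 at 1.2 and 0.6, with 0 false regions. The simulated peaks were broader than the regions found here, their tile noise was independent and their background was the same on both arrays. The measured background was mostly specific to each array, so these rates need not hold for the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

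The planned tests of gene starts, gene lists, summits near gene starts and the SigD promoter motif, and the GC correction, were not run because they need gene positions or sequence. The rule for named genes, fixed in advance, took the genes nearest to the 20 strongest regions and the 20 strongest gene starts, with list members and sigma factor genes. It could not be applied because the files do not pair probe identifiers with gene names and the reference table given is of another strain of the species. The probes named below were therefore chosen after their values were seen. The alternatives covered background correction, normalization, centring, probe filters, variance priors, thresholds, windows, run lengths and single arrays. The files lack mean signals, so normexp and the setting without background correction used median signals. Neither these nor the background-subtracted signals carry the dye normalization of the scanner software.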

Results

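SigD is an extracytoplasmic function sigma factor, a protein that directs RNA polymerase to promoters. On each of 2 arrays, anti-FLAG IP DNA of SigD-FLAG cells was compared with reference DNA of the same kind of culture. Each array held 18462 forward-strand tiles, 18449 reverse-strand tiles, 3278 gene probes and 15 further probes spotted 10 times each. The centred log2(IP/reference) values had an SD of 0.18 on both arrays. Gene probes spotted more than once differed between spots by an SD of 0.064 on array 1 and 0.054 on array 2.

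The comparison of IP with reference DNA asked where along the chromosome SigD-FLAG was enriched. A few sharp maxima stood at the same places on both arrays, and array 1 held further ones. At log2 of 1 or more on each array there were 2 enriched regions. The stronger, region 1, had its summit at forward tile 17070, at 92.5% of the tile numbering. Its running mean log2 ratio was 1.94 ± 0.74 (SD, n = 2), with 2.46 on array 1 and 1.41 on array 2, or 5.50-fold and 2.67-fold. Region 2 had its summit at forward tile 13732, at 74.4% of the numbering, with 1.62 ± 0.55 (SD, n = 2), or 4.02-fold and 2.34-fold on the arrays. None of the 1000 rotations of array 2 gave 2 regions, and the highest count was 1 (one-sided permutation p = 0.001, the smallest these rotations can give). Array 2 alone held 2 such regions, so few rotations could reach that count. The p shows only that maxima of the arrays coincide. Rotation also breaks any probe or reference effect shared by both arrays, so it cannot separate enrichment from such an effect. There were 0 mirrored regions, but this says nothing about chance. The lowest running mean of array 1 was -0.36, so none could arise. With a running mean over tiles within 2.5 tile numbers in place of 1.5, with runs of at least 8 tiles, or at log2 of 1.5, 0 regions were left. Normexp background correction, on median signals, found neither region and took their heights to 0.90 and 0.32. Without background correction or on background-subtracted signals 1 region was left, although the heights moved little, to 1.93 and 1.87 at region 1 and to 1.58 and 1.54 at region 2. These settings and normexp also leave out the dye normalization of the scanner software. Their difference from the main setting is therefore not that of background handling alone. The setting without background correction used the same median signals as normexp, also without dye normalization, and its heights were 1.93 and 1.58. Missing dye normalization therefore does not by itself explain the loss of height with normexp.

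A lower threshold of 0.6, planned as an alternative, gave 6 regions, including both of the above. At most 1 arose in any rotation (one-sided permutation p = 0.001, again the smallest possible). This p too shows only that the maxima coincide, and it cannot separate enrichment from an effect shared by both arrays. The 0 mirrored regions at this threshold again say nothing about chance, since no run of array 1 reached -0.6. Region 3 lay at 5.86% of the numbering with a mean log2 ratio of 1.39 ± 0.52 (SD, n = 2). Region 4 lay at 27.8% with 1.29 ± 0.37, and region 5 at 92.7%, close to region 1, with 1.17 ± 0.57. Region 6, at 14.2%, was the lowest at 0.79 ± 0.21. Forward and reverse tiles, which are separate probes, were both enriched. At the summit of region 1 their means over the arrays were 2.05 and 1.61, and at region 2 they were 1.78 and 1.51. The running mean used to call regions pools both strands, so high values on both are partly built into the call. The 6 regions spanned between 1 and 2 tile numbers from first to last tile above the threshold. Over the 36 tiles within 1 tile number of these summits, the median reference signal was 45.0% of the array median on array 1 and 61.4% on array 2, and the median IP signal was 139.6% and 122.2%. Tiles with an outlier flag, which gave no ratio, are included: 10 on array 1 and 6 on array 2. By these medians, the low reference made up more of the log2 ratio than the raised IP on both arrays.

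**Figure D1:**
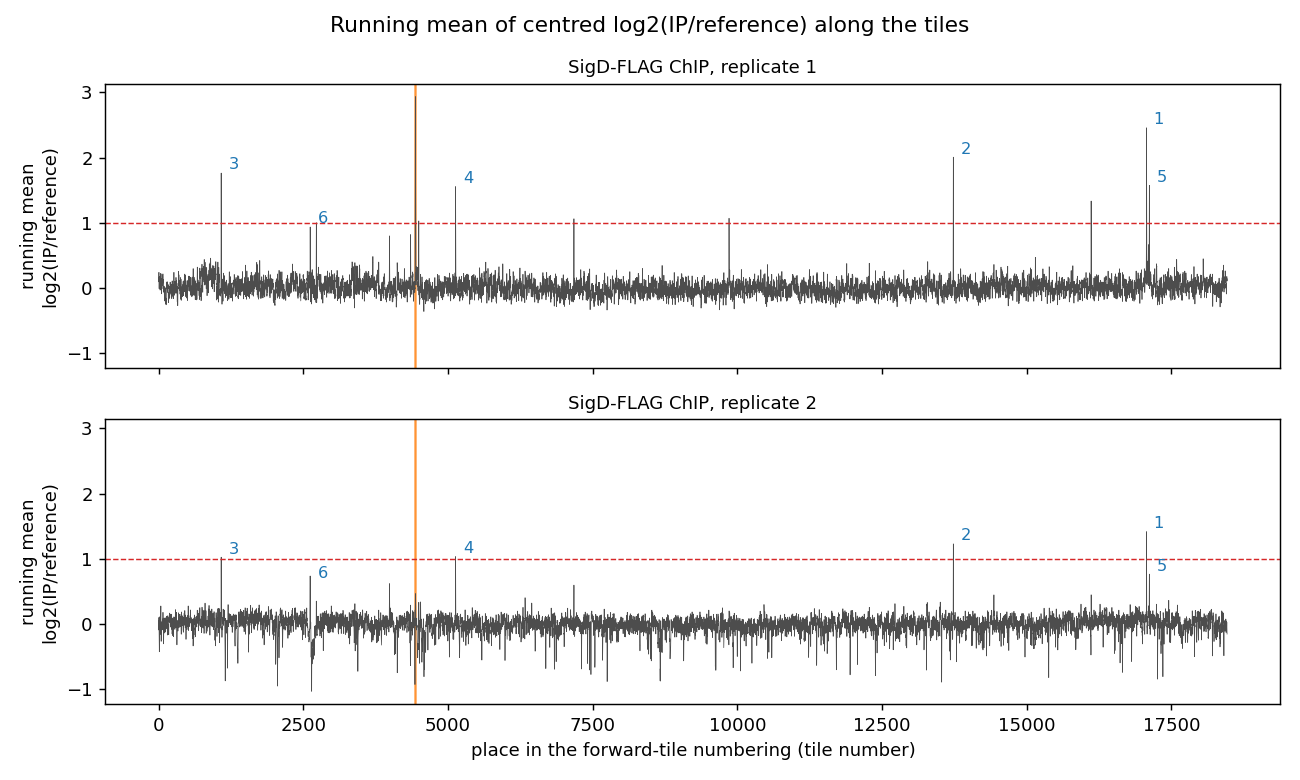
Running mean of centred log2(IP/reference) (vertical axis) against place in the forward-tile numbering (horizontal axis) for replicate 1 (top) and replicate 2 (bottom). Blue numbers mark the 6 regions at log2 of 0.6 or more on both arrays, the dashed line is log2 of 1, and the orange band is a stretch with low reference signal; region 1 reached 2.46 on replicate 1 and 1.41 on replicate 2.

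All 6 regions were higher on array 1 than on array 2. The median height was 1.67 on array 1 and 1.03 on array 2, and the median of the array 2 to array 1 ratio of log2 heights was 0.60. Taken singly, array 1 held 8 regions at log2 of 1 or more, of which 5 were among the 6 and 1 lay in a stretch with low reference signal, and array 2 held 2, both of which overlapped an array 1 region. At 0.6, array 1 held 14 and array 2 held 6, all 6 of which overlapped an array 1 region.

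**Figure D2:**
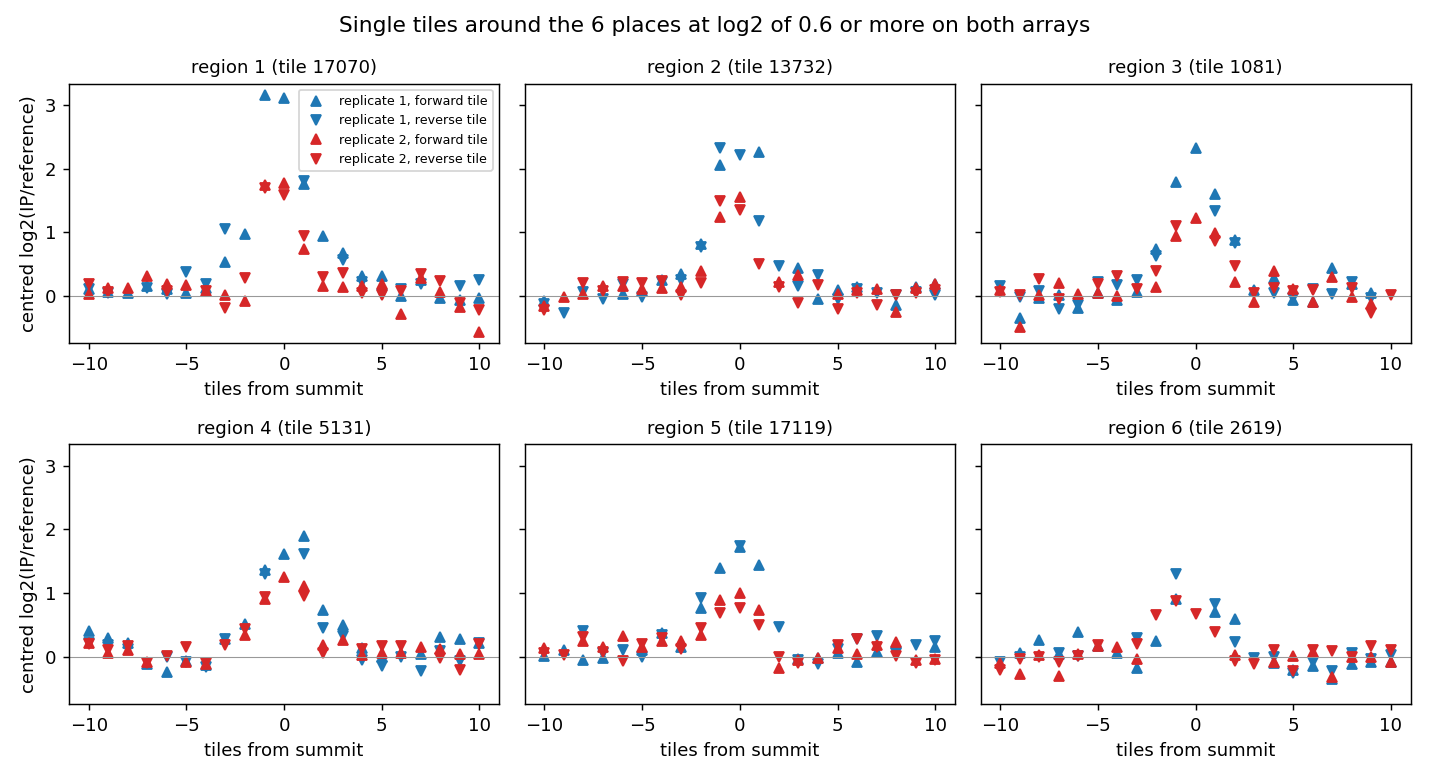
Centred log2(IP/reference) of single tiles (vertical axis) against distance in tile numbers from the summit (horizontal axis) for the 6 regions; blue is replicate 1, red is replicate 2, upward triangles are forward tiles and downward triangles reverse tiles. At 5 of the 6 regions both strands averaged 0.6 or more on both arrays, region 6 lacking forward values on replicate 2 next to its summit, and replicate 1 stands above replicate 2 at region 1 (running means 2.46 and 1.41). The regions were called on a running mean over both strands.

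Probe by probe, limma with the trend and robust options called 0 of 32912 probes above the reference and 0 below. At an unadjusted p under 0.05 with a mean log2 ratio of 1 or more there were 11 probes above and 0 below, and eBayes without both options called 35 above and 1 below. Without the trend alone it called 6 above, and without the robust option alone 0. In the values of these fits the lowest centred ratio was -0.66 on array 1 and -1.45 on array 2. A mean of -1 or less was therefore hardly reachable, and the low counts below say little about chance. With both options kept, quantile normalization gave 20 above, background-subtracted signals gave 4, and normexp gave 812 above and 3 below. A trend on intensity gave 7 above. The SE of forward tile 17070, whose mean log2 ratio was 2.44, was 2.89 with both options, 0.61 without the trend and 0.20 without both. Of the 32 tiles called without both options, 21 lay within 3 tiles of a region summit, 6 in a stretch with low reference signal at 24.0% of the numbering, and 5 elsewhere. Tile calls and regions rest on the same log2 ratios, so this overlap is largely built in.

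Of the 3188 gene probes tested, 0 were called with both options, 0 without the trend alone and 3 without both. With both options, 1 had an unadjusted p under 0.05 and a mean log2 ratio of 1 or more. Quantile normalization gave 2 calls and normexp 80. The gene probes ranked 1, 3 and 4 by mean log2 ratio, at 1.68, 1.39 and 1.35, were the 3 with reference signal under 15% of the array median on both arrays. They lay between 2.85 and 2.94 on array 1 but between -0.23 and 0.52 on array 2, and stand from 23.8% to 23.9% of the gene probe numbering. The highest of the other gene probes was CGR2390, with a mean log2 ratio of 1.66 ± 0.61 (SD, n = 2; limma adjusted p = 0.40 with both options, 0.32 without the trend and 8.6e-05 without both). It stands at 72.9% of the gene probe numbering, 1.47 percentage points from region 2 in the tile numbering. Probe CGR0185, at 5.64% of the gene probe numbering, had 1.17 ± 0.74 (SD, n = 2), with 1.69 on array 1 and 0.645 on array 2. Its limma adjusted p was 0.28 with both options. Region 3 lies at 5.86% of the tile numbering. CGR2390 and CGR0185 were each the highest gene probe within 2 percentage points of the region named. A place in percent is not a map position, so these values do not show that a gene probe lies in a region. Near region 1, the strongest, the highest gene probe within 2 percentage points had a mean log2 ratio of 0.34, and near region 4 it was 0.29. The files do not pair these identifiers with gene names.

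Across the 32912 probes, the arrays correlated with a Pearson r of 0.37 and a Spearman rho of 0.36, and the SD of the difference was 0.20. Probes are not independent replicates, so no p-value is given. On tiles outside the regions and the low-reference stretch, r was 0.33 for the same tile on both arrays. Forward tiles correlated with the reverse tiles at the same place of the same array with r of 0.45 on array 1 and 0.51 on array 2. Across arrays, r was 0.071 for forward tiles of array 1 with reverse tiles of array 2, and 0.050 the other way round.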

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

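Settings on background-subtracted signals, on a prior variance trend over intensity, without the trend alone, without the robust option alone and without low-reference probes were chosen after seeing the data. The 2 enriched regions stayed at 2 with loess, mode centring, outlier spots kept and the running median, and both summits were found each time. Loess tests little, since the scanner software had already applied a lowess fit. It moved the height of region 1 only from 1.9365 to 1.9377. With quantile normalization there were 3 regions. The count was 6 at log2 of 0.6, 4 with a running mean within 0.75 tile numbers, 4 with the mean of both arrays (1 of them in the low-reference stretch), 1 without background correction, 1 on background-subtracted signals, and 0 at log2 of 1.5, with a running mean within 2.5 tile numbers or with runs of at least 8 tiles. Normexp gave 5 regions, none of which was among the 6, and took the heights of regions 1 and 2 to 0.90 and 0.32. The cause of these changes was not tested. Array 2 alone gave 2 regions and array 1 alone 8, of which 1 lay in the low-reference stretch and 5 were among the 6 regions at 0.6. Probe calls above the reference rose from 0 to 35 with eBayes without trend and robust options and to 6 without the trend alone. A trend on intensity gave 7, all 7 among those 35. Quantile normalization, which gives both arrays the same distribution of values, gave 20. Background-subtracted signals gave 4 and normexp 812. Single arrays, which allow no test, held 18 (array 2) and 65 (array 1) probes at log2 of 1 or more. Calls below the reference rose from 0 to 1 with eBayes without both options and 3 with normexp; array 1 alone held 0 and array 2 alone 30. Gene probe calls rose from 0 to 3 with eBayes without both options, 2 with quantile normalization and 80 with normexp; array 2 alone held 1 and array 1 alone 9. The other settings gave 0 calls. The value table holds the same log ratios, removing saturated probes removed nothing and removing dim probes took away 2 probes, so these say nothing about stability. The GC correction and the settings of gene starts, gene lists, summits and the motif were not run. No paired analysis was possible because there is a single group.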

Other observations

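All tests of explanations in this part were chosen after the results were seen. Array 2 held 29 runs of at least 4 tiles with a running mean log2 ratio of -0.6 or less, and array 1 held 0. In their 162 tiles the median log2 ratio was -0.80 on array 2 and 0.06 on array 1, with -0.81 on forward and -0.78 on reverse tiles of array 2. Reference signal there was 92.8% of the array median on array 2 and 64.6% on array 1, and IP signal was 53.5% and 66.9%. No explanation was tested.

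A stretch from forward tile 4432 to 4442 held 10 tiles with reference signal under 15% of the array median on both arrays, interleaved with 12 tiles of ordinary signal. The low tiles had a median log2 ratio of 2.82 on array 1 and 0.61 on array 2, where IP and reference signal were 0.894% and 0.562% of the array median. On array 1 their IP signal was 42.4% of the array median against 5.47% for the reference, so a ratio made only by dividing by a very low reference, with no such DNA in the IP, is argued against. The interleaved tiles had a median of 0.52 on array 1 and -0.062 on array 2. On array 2 they were level with the 8 tiles of the upper flank, at -0.05, and stood 0.61 above the 8 of the lower flank, which were themselves low at -0.67, with reference signal at 91.0% and IP signal at 55.6%, much as in the low runs of that array. These values do not decide on SigD-FLAG binding there in both experiments. DNA that differed between cultures or preparations was not tested.

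At the 6 regions the reference signal was low: 45.0% of the array median on array 1 and 61.4% on array 2 over 36 tiles. Dye normalization as the whole cause is argued against, since the background-subtracted reference was 48.7% on array 1. Forward tiles at regions chosen on reverse tiles alone were at 47.1% on array 1. This argues against selection on the noise of single tiles as the whole cause there. On array 2 these forward tiles were at 62.5%, which does not decide. Selection on signal shared by both strands of an array stays open, since their ratios correlated outside the regions (r of 0.45 and 0.51). An equal shortage of this DNA in both references stays open: the median array 1 to array 2 ratio of reference signal was 0.71, with 4 of 6 regions under 0.8, but 0.82 at forward tiles of regions chosen on reverse tiles. Competition of abundant IP DNA for the probe stays open too. The reference was lower on the array with more IP signal in 88.9% of region tiles and 29.2% of tiles outside, but all 6 regions were higher on array 1, and that difference largely fixes the share.

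The lower heights on array 2, with a median ratio of 0.60 to array 1, could come from a compression of all its log ratios, and this could not be decided. The MAD of the running mean outside regions was 0.95 times that of array 1. That spread is mostly specific to each array, so it need not follow the scale of the enrichment. The SD ratio, tried first, was 1.16, and 1.05 without the low runs of array 2 and 15 tiles on each side. A weaker immunoprecipitation in the second experiment was not tested.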
